A study of Homo sapiens with 24 samples.

How the data were processed

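The study measured RNA in 24 patient-derived xenograft tumours, 8 from mice given vehicle, 8 given BMS-986365 and 8 given enzalutamide. The compound name differs between the sample labels (CC-94676) and the design text (BMS-986365), which are names of the same compound. Per the labels, RNA was made into strand-specific, poly-A selected libraries with ERCC spike-in. The deposited values are expected counts per gene, made with STAR (version not stated) and RSEM 1.3.0 on GRCh38, per the submitters' processing notes. The annotation release and read filters are not given in the sources used here. The sample descriptions name every count column with the ending Human, but whether and how mouse reads were set apart is not stated. The table held 58394 entries, 92 of them spike-in sequences, which were 0 in every sample and could not be used for scaling. Of the 58302 gene IDs, 98.7% (57532) matched a gene name in the human gene name table, and 99.5% were found in GENCODE release 29 (GRCh38), from which coordinates were taken. RSEM shares reads between near-identical genes by a model, so values of members of multigene families such as the UGT2B genes are less certain than others.

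Samples were grouped by their treatment label, and replicates were numbered 1 to 8 in accession order, so that a number only names a sample and never pairs samples. Expected counts were rounded to whole numbers. Total counts ran from 18634881 to 27751997 per sample, and the 10 most abundant genes took 5.2 to 6.58% of them. The analysis used R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0 and cluster 2.1.8.1, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Genes were kept by edgeR's filterByExpr (17603 genes), scaled by TMM and tested with edgeR's quasi-likelihood F-test with robust estimation. P-values were adjusted by Benjamini-Hochberg over all tested genes, at a threshold of 0.05 with no minimum fold. All 24 samples entered 1 model with treatment and expression cluster as additive terms, so the 3 treatments share the estimate of the spread. Clusters came from average-linkage clustering on Pearson correlation of log2 CPM (prior count 2) of the 1000 most variable genes, cut into 2. The rule allowed the term only where the mean silhouette width was at least 0.3 and each treatment had at least 2 samples in each cluster. Interaction terms tested whether a treatment effect differed between clusters, and each cluster was also fitted alone. CPM values are means ± SD over samples, and fold changes are given ± SE.

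The design, the tests, the alternatives (except one named in the closing section), the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls per comparison among called genes with a mean log2 CPM of at least 1, a gene symbol of a known gene and the same sign in each cluster, and up to 4 members per list with the smallest p. Some genes within the rule are not reported here. Y-linked genes and XIST, HLA genes and genes often deleted in the germline were left out of naming and of clustering. The 25 gene lists came from textbook knowledge and 23 had the minimum of 3 tested members. Lists overlap: NDRG1, for example, is both an androgen target and a hypoxia gene. Lists were tested with camera (preset inter-gene correlation 0.01, and again with an estimated correlation) and with fry, which tests whether a list's genes move on balance one way. Their p-values were adjusted over the lists within each comparison. A sample count such as 7 of 8 gives the treated samples on the stated side of the vehicle mean of their own cluster.

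The alternatives were no cluster term, each cluster alone, 3 surrogate variables in place of the cluster term, DESeq2 size factors, library size alone, no filter on low counts (33842 genes), at least 1 CPM in 8 samples (15647 genes), the DESeq2 Wald test, voom, a minimum fold of 2, only the samples of the 2 treatments compared, and leaving out each of the 24 libraries. The edgeR test was checked on counts simulated from edgeR's own fit and estimates of the spread, for all 17603 genes with 200 changed genes. The changed genes were drawn from those with a mean log2 CPM of at least 1, so the shares below do not cover genes with lower counts. Each gene was simulated independently, so correlation between genes is not covered either. The simulated changes were also far fewer than the genes called against vehicle in the data. With fewer changed genes the adjustment is stricter, so the shares for those comparisons may be too low. For BMS-986365 against vehicle the edgeR test recovered 62.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 3-fold. For enzalutamide against vehicle the shares were 74.6%, 89.6% and 95.5%, and for BMS-986365 against enzalutamide 64.2%, 92.5% and 97%. The simulated comparisons gave 8, 5 and 5 false calls with edgeR (of 178, 178 and 174 calls) and 25, 27 and 21 with DESeq2 (of 204, 206 and 196). At these depths and 8 samples per treatment, 1.5-fold changes can be missed. Similarity of the compounds was set against 20 simulations of unchanged groups with the same vehicle samples and 36 splits of the vehicle samples into sets of 4 balanced over clusters.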

Results

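RNA was sequenced from 24 subcutaneous tumours carried by immunodeficient NOG mice. The tumours were patient-derived xenografts, human tumour tissue grown in mice, of metastatic castration-resistant prostate cancer, a disease that progresses under low androgen and usually still depends on androgen signalling. Each treatment had 8 samples: vehicle, BMS-986365 at 60 mg/kg and enzalutamide at 50 mg/kg, both inhibitors of androgen signalling. Doses were given by mouth once a day for 7 days, and tumours were taken 6 h after the final dose. The design text named 2 tumour models, whereas the labels of all 24 samples named 1. Nothing in the labels ties each sample to its own mouse, so p-values measure the spread between these samples, which may in part be technical. Total counts ran from 18634881 to 27751997 per sample (median 23715847). Their means were 22436336 ± 2287163 for vehicle, 23805626 ± 1770639 for BMS-986365 and 22922792 ± 3346728 for enzalutamide (SD, n = 8 each). Between 22786 and 24511 genes had a count in a sample. Mitochondrial genes took 4.54 to 6.06% of the counts.

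The samples fell into 2 expression clusters of 12, found without use of the treatment labels (mean silhouette width 0.512). Each cluster held 4 samples of every treatment: replicates 1 to 4 in cluster A and replicates 5 to 8 in cluster B. The first principal component separated the clusters and carried 39.4% of the variance, and the second (17.2%) separated treated from vehicle samples. No treatment, dose or model label separates these sets, and whether they are groups of the study is not stated. They follow the running numbers of the sample titles, as 2 successive blocks that each hold every treatment. Fits of all samples hold a cluster term unless an alternative is named, and values within each cluster are given for some genes and lists beside the pooled ones. In all 36 pairs of samples that shared a treatment and a cluster the counts differed by more than sampling noise (chi-square per degree of freedom 11.1 to 93.9), so no library was counted as a copy of another.

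**Figure D1:**
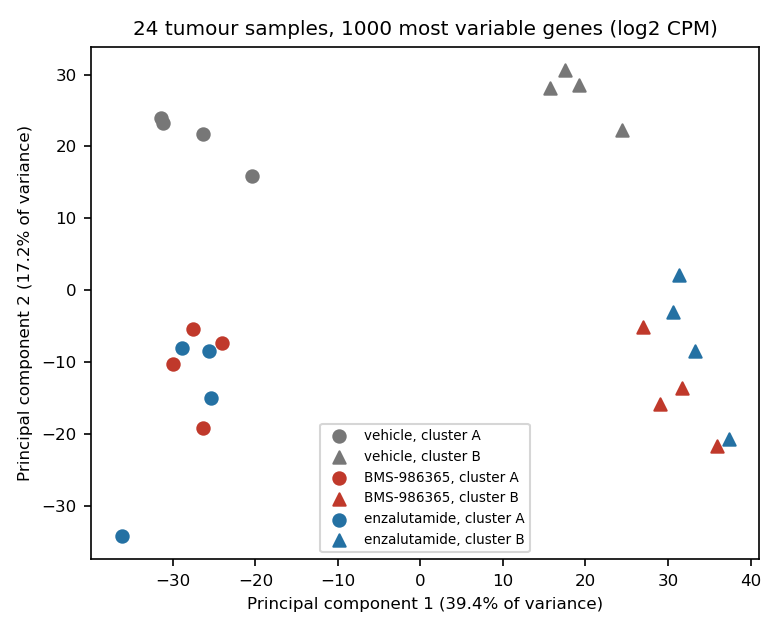
Scores of the 24 tumour samples on the first 2 principal components of log2 CPM of the 1000 most variable genes, coloured by treatment, with 1 marker shape per cluster. The first component (39.4% of the variance) separates the clusters and the second (17.2%) separates vehicle from treated samples.

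The first comparison asked what 7 days of BMS-986365 did to tumour RNA. Genes that androgen induces were mostly lower with BMS-986365, but not all of them. CHRNA2, a nicotinic receptor subunit induced by androgen, fell to 2.8 ± 1.4 CPM (counts scaled to 1000000 per sample) from 31.4 ± 11.9 CPM in vehicle (SD, n = 8 each, as for all CPM values below unless a cluster is named). Its log2 fold change was -3.46 ± 0.41 (SE), with an edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 1.49e-06, and it was lower in 8 of 8 samples. SLC45A3, which encodes prostein, fell by 1.79 ± 0.28 on the log2 scale. The methyltransferase gene GNMT (-2.05 ± 0.25) and the chaperone gene FKBP5 (-0.95 ± 0.21) fell as well. Of the 29 tested members of the list of core androgen targets, 16 fell and 2 rose (17 and 2 adjusted over the list alone), with a median log2 fold change of -0.70. The risers were MED28 (0.31) and PTGER4 (0.79), both named after their values were seen. The call for PTGER4 (edgeR adjusted p = 0.0498) was lost in 17 of 24 fits that each left out 1 library. KLK3, the gene of prostate-specific antigen (chromosome 19, 50854915 to 50860764), gave 1328 ± 568 CPM against 1330 ± 458 CPM in vehicle (log2 fold change -0.09 ± 0.31, edgeR adjusted p = 0.831). KLK3 was also named after its values were seen, and its log2 fold change was 0.54 in cluster A and -0.70 in cluster B. With surrogate variables in place of the cluster term it was 0.53 (edgeR adjusted p = 0.0336). TMPRSS2, a protease gene named in the same way, gave -0.36 ± 0.18 (edgeR adjusted p = 0.116), but -0.46 without vehicle replicate 1 (edgeR adjusted p = 0.0317). In cluster B alone TMPRSS2 was at -0.73 (edgeR adjusted p = 0.00375), and in cluster A at 0.00.

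The wide androgen response list moved the same way: 53 of 99 tested members fell and 8 rose (56 and 9 adjusted over the list alone). Its member SORD, which makes fructose from sorbitol, fell by 1.65 ± 0.12 on the log2 scale. Of 12 tested genes that androgen represses, 8 rose and 1 fell (8 and 1 adjusted over the list alone). FOLH1, which encodes prostate-specific membrane antigen, rose to 4024 ± 911 CPM from 2791 ± 670 CPM (0.54 ± 0.07, edgeR adjusted p = 1.96e-06), and the chaperone gene CLU rose by 1.12 ± 0.20. BCL2, an inhibitor of apoptosis named after its values were seen, was the member that fell (-1.08). Camera adjusted p-values were 0.000107 for the core androgen targets, 3.71e-08 for the wide list and 0.00504 for the repressed genes. These calls were lost with estimated correlations, at adjusted p = 0.392, adjusted p = 0.198 and adjusted p = 0.153 with an estimated correlation. Luminal lineage genes went both ways, with 5 of 18 higher and 5 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.913). Among them SPDEF, an epithelial transcription factor, fell by 0.75 ± 0.09 and GATA2, a zinc finger transcription factor, rose by 1.27 ± 0.25.

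Genes of fatty acid synthesis, cholesterol synthesis and the hypoxia response were mostly lower with BMS-986365. FASN, the fatty acid synthase, fell to 975 ± 201 CPM from 3202 ± 746 CPM (log2 fold change -1.71 ± 0.14, edgeR adjusted p = 1.21e-08). ACLY, which supplies acetyl-CoA for lipid synthesis, fell by 1.23 ± 0.12. Of 14 fatty acid synthesis genes 11 fell and 1 rose (11 and 1 adjusted over the list alone), the riser being ACACB (0.32), named after its values were seen. Of 25 cholesterol synthesis genes 23 fell and 1 rose (24 and 1 adjusted over the list alone), with a median log2 fold change of -0.98. SQLE, which makes squalene epoxide, fell by 1.40 ± 0.17. The riser was TM7SF2 (1.14), a sterol reductase named after its value was seen. Of 18 hypoxia genes 13 fell and 0 rose (13 and 1 adjusted over the list alone). LDHA, which makes lactate, fell by 1.34 ± 0.18 and NDRG1, also an androgen target, by 1.21 ± 0.16. Camera adjusted p-values were 1.06e-05 for fatty acid synthesis, 5.23e-12 for cholesterol synthesis and 1.04e-06 for hypoxia. With estimated correlations they became adjusted p = 0.153, adjusted p = 0.153 and adjusted p = 0.23 with an estimated correlation.

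All 30 tested cell cycle genes were lower with BMS-986365 (30 also adjusted over the list alone), with a median log2 fold change of -1.06. MKI67, the Ki-67 gene, fell to 74.1 ± 43.2 CPM from 156 ± 34.3 CPM (-1.20 ± 0.31, edgeR adjusted p = 0.00366; named after its values were seen). PLK1, a mitotic kinase, fell by 1.33 ± 0.27 and MCM6, part of the replicative helicase, by 0.58 ± 0.11. The calls came mostly from cluster B, where 29 of 30 passed the threshold (median -1.52), against 1 of 30 in cluster A (median -0.54). Of 22 genes of ribosome biogenesis and MYC targets all 22 fell (22 adjusted over the list alone, median -0.46), with 17 past the threshold in cluster A and 20 in cluster B. GNL3, a nucleolar GTPase, fell by 0.63 ± 0.05. Of 10 polyamine genes 6 fell (6 adjusted over the list alone), and SRM, the spermidine synthase, fell by 0.97 ± 0.13. Camera adjusted p-values were 3.38e-10 for the cell cycle, 9.96e-12 for ribosome biogenesis and 0.00559 for polyamines. With estimated correlations they became adjusted p = 0.397, adjusted p = 0.153 and adjusted p = 0.153 with an estimated correlation.

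Of 23 interferon genes 11 rose and 0 fell with BMS-986365 (13 higher adjusted over the list alone), with a median log2 fold change of 1.19. IFIT3, an antiviral protein gene, rose by 1.91 ± 0.60, and IRF9, part of the interferon-activated transcription complex, rose by 0.84 ± 0.23 (edgeR adjusted p = 0.0061). The camera adjusted p was 5.32e-05, and adjusted p = 0.571 with an estimated correlation. In cluster A alone 0 of 23 passed (median 1.72) and in cluster B alone 9 passed (median 0.85). Single libraries moved the count: it was 7 without vehicle replicate 1, 2 or 4 or BMS-986365 replicate 5, 17 without vehicle replicate 8, and 21 without enzalutamide replicate 4, which enters the shared estimate of the spread.

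The largest rise with BMS-986365 was that of NXPE1, which has no settled function. NXPE1 (chromosome 11, 114521645 to 114559895) rose to 11.5 ± 3.52 CPM from 0.439 ± 0.224 CPM (log2 fold change 4.69 ± 0.28, edgeR adjusted p = 1.32e-10, higher in 8 of 8 samples). GPA33, a surface antigen of intestinal epithelium, rose to 64.4 ± 27.6 CPM from 6.6 ± 3.43 CPM (3.35 ± 0.27). SLPI, a secreted protease inhibitor, rose by 3.35 ± 0.40, and PIGR, the receptor that carries IgA across epithelium, rose to 1542 ± 753 CPM from 271 ± 143 CPM (2.61 ± 0.32). APOL4 (2.86 ± 0.31), the interferon-induced XAF1 (2.81 ± 0.49), FAM3D (2.72 ± 0.29) and GC, the vitamin D binding protein gene (2.69 ± 0.32), completed the rises. The largest falls included those of RPE65, a retinoid isomerase gene (-3.83 ± 0.48), CHRNA2, ALOX15B, a lipoxygenase that fell to 117 ± 38.5 CPM from 907 ± 378 CPM (-2.90 ± 0.27), CCNP (-2.59 ± 0.40), the desmosome gene PKP1 (-2.48 ± 0.40), ANPEP (-2.43 ± 0.49) and the haem oxygenase gene HMOX1 (-2.21 ± 0.58, edgeR adjusted p = 0.00442).

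The remaining lists had no camera call with BMS-986365 over all samples. Neuroendocrine genes had 0 of 17 members past the threshold (0 adjusted over the list alone, camera adjusted p = 0.725). In cluster A alone 1 was lower (median -0.91), and in cluster B alone 3 were higher (median 1.92, camera adjusted p = 0.06). Glucocorticoid receptor targets had 2 of 15 higher and 2 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.725), with KLF9 at 0.69 ± 0.18 and the metallothionein gene MT1X at -0.81 ± 0.17. Basal epithelial genes had 2 of 9 higher (2 adjusted over the list alone; camera adjusted p = 0.225), the integrins ITGB4 (0.67 ± 0.15) and ITGA6 (0.48 ± 0.11). Genes of epithelial to mesenchymal transition had 1 of 9 higher, ZEB1, and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.913). The 2 were SNAI2 and VIM, whose calls were lost in 5 and 7 of 24 fits that each left out 1 library. Endoplasmic reticulum stress genes had 3 of 17 lower (2 adjusted over the list alone; camera adjusted p = 0.426), integrated stress response genes 5 of 16 lower (5; camera adjusted p = 0.13) and p53 targets 5 of 16 lower and 2 higher (7 and 2; camera adjusted p = 0.225). Camera called the integrated stress response list in cluster B alone (7 lower, adjusted p = 0.0412, and adjusted p = 0.485 with an estimated correlation). It also called the list without enzalutamide replicate 4 (adjusted p = 0.0337), where only the preset correlation was used. The p53 target MDM2 fell by 0.42 ± 0.08, and fry gave that list an adjusted p of 0.00814. Steroid enzymes had 3 of 10 higher and 2 lower (3 and 4; camera adjusted p = 0.913), with HSD17B3, which makes testosterone, at 1.86 ± 0.35.

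Markers of other cell types went both ways with BMS-986365, measured on human genes, whereas the cells of the host are mouse cells. Fibroblast and smooth muscle markers had 2 of 6 higher (2 adjusted over the list alone; camera adjusted p = 0.225, fry adjusted p = 0.0112), TAGLN (0.59 ± 0.11) and COL1A1 (0.68). In cluster B alone camera called this list (median 0.78, adjusted p = 0.0412, and adjusted p = 0.413 with an estimated correlation). COL1A1 was no longer called without BMS-986365 replicate 7 (0.48, edgeR adjusted p = 0.0675). Of 4 endothelial markers ENG rose by 0.56 ± 0.18 and VWF fell by 2.59 ± 0.43 (1 and 1 adjusted over the list alone; camera adjusted p = 0.913, median 0.18, mean -0.42). Myeloid markers had 1 of 3 higher, LYZ (1; camera adjusted p = 0.398), and hepatocyte and keratinocyte markers 1 of 5 lower, KRT10 (0; camera adjusted p = 0.977). The calls of LYZ and KRT10 were lost in 6 and 12 of 24 fits that each left out 1 library. Lymphocyte markers and muscle and adipocyte markers had fewer than 3 tested members and were not tested.

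Over all 17603 tested genes, edgeR called 7539 with BMS-986365 against vehicle (42.8%), of which 3645 were higher and 3894 lower, and 713 higher and 442 lower by at least 2-fold. Cluster A alone gave 2414 genes (1084 higher, 1330 lower) and cluster B alone 6006 (2919 higher, 3087 lower). With library size in place of TMM scaling the split was 4945 higher against 2774 lower, with a shift of 0.0846 in the median log2 fold change. Camera called 10 of 23 tested lists, and 0 of them kept the call with an estimated correlation (lowest adjusted p = 0.153 with an estimated correlation), while fry called 12, including all 10.

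**Figure D2:**
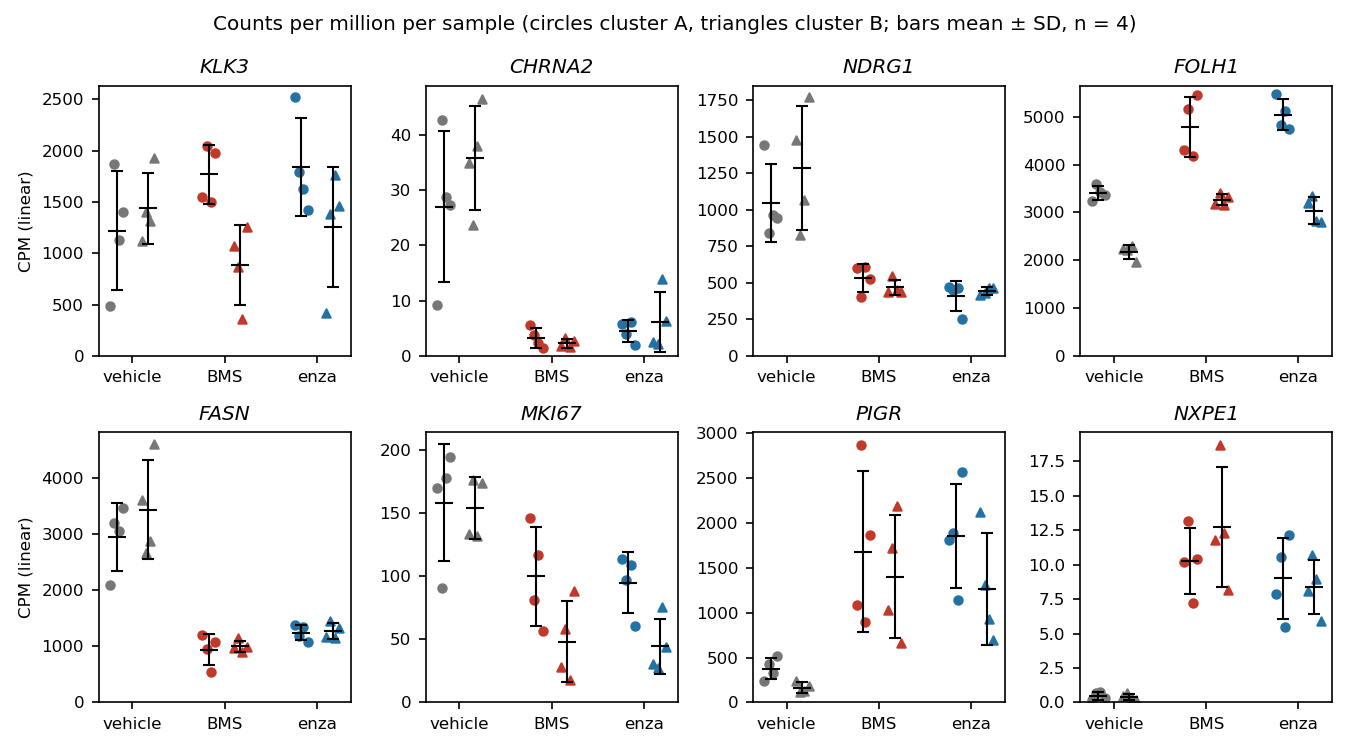
CPM per sample on linear axes from 0 for 8 genes, by treatment, with circles for cluster A, triangles for cluster B and bars for the mean ± SD of 4 samples. FOLH1 lies at 4024 ± 911 CPM with BMS-986365 and 4040 ± 1107 CPM with enzalutamide against 2791 ± 670 CPM in vehicle, and FASN at 975 ± 201 CPM with BMS-986365 and 1262 ± 131 CPM with enzalutamide against 3202 ± 746 CPM in vehicle (n = 8).

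The second comparison asked the same of enzalutamide. Core androgen targets past the threshold with enzalutamide were lower with 1 exception. NDRG1 fell to 426 ± 72.4 CPM from 1166 ± 351 CPM (-1.45 ± 0.16, edgeR adjusted p = 8.06e-07) and CHRNA2 to 5.33 ± 3.89 CPM from 31.4 ± 11.9 CPM (-2.55 ± 0.39). Of 29 core targets 14 fell and 1 rose, MED28 (0.26), with 15 and 2 adjusted over the list alone. KLK3 was at 1548 ± 584 CPM against 1330 ± 458 CPM (0.16 ± 0.30, edgeR adjusted p = 0.709; 0.59 in cluster A and -0.20 in cluster B; 0.69 with surrogate variables, edgeR adjusted p = 0.00869) and TMPRSS2 at -0.29 ± 0.18 (edgeR adjusted p = 0.2), both named after their values were seen. Of 99 wide list genes 51 fell and 8 rose (54 and 8 adjusted over the list alone), with SORD at -1.31 ± 0.12. Of 12 androgen-repressed genes 8 rose and 0 fell (8 and 1 adjusted over the list alone). FOLH1 rose to 4040 ± 1107 CPM from 2791 ± 670 CPM (0.52 ± 0.07, edgeR adjusted p = 5.24e-06), CLU by 1.10 ± 0.20 and UGT2B15, which inactivates androgens, by 2.14 ± 0.47. Camera adjusted p-values were 0.000433, 7.98e-08 and 0.00251 for these 3 lists. With estimated correlations they became adjusted p = 0.433, adjusted p = 0.205 and adjusted p = 0.118 with an estimated correlation. Luminal genes had 4 of 18 higher and 4 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.782), with GATA2 at 1.18 ± 0.25 and SPDEF at -0.85 ± 0.09.

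Genes of fatty acid synthesis, cholesterol synthesis, hypoxia, the cell cycle and ribosome biogenesis were mostly lower with enzalutamide too. FASN fell to 1262 ± 131 CPM from 3202 ± 746 CPM (-1.34 ± 0.14, edgeR adjusted p = 5.12e-07), and of 14 fatty acid synthesis genes 9 fell and 0 rose (9 and 1 adjusted over the list alone). Of 25 cholesterol synthesis genes 20 fell and 1, TM7SF2, rose (22 and 1 adjusted over the list alone). Of 18 hypoxia genes 14 fell and 1 rose, P4HA2, a collagen-modifying enzyme (14 and 1 adjusted over the list alone). The P4HA2 rise of 0.56, named after its value was seen, was 0.37 without enzalutamide replicate 4 (edgeR adjusted p = 0.0295). All 30 cell cycle genes fell (30 adjusted over the list alone, median -1.05), MKI67 to 69.7 ± 34.4 CPM from 156 ± 34.3 CPM. In cluster A 2 of the 30 passed the threshold and in cluster B 27. Of 22 ribosome biogenesis and MYC target genes 21 fell (22 adjusted over the list alone, median -0.41), with 18 past the threshold in cluster A and 16 in cluster B. Of 10 polyamine genes 4 fell (5 adjusted over the list alone), and SRM fell by 0.74. Camera adjusted p-values were 0.000142 for fatty acid synthesis, 4.6e-11 for cholesterol, 2.6e-07 for hypoxia, 1.19e-10 for the cell cycle, 2.24e-11 for ribosome biogenesis and 0.0243 for polyamines. All were lost with estimated correlations, with adjusted p = 0.421 for the cell cycle and adjusted p = 0.205 for the other lists with an estimated correlation.

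Interferon-induced genes had most of the largest rises with enzalutamide, a rank that rested on 1 library. SAMD9L reached 70.1 ± 151 CPM against 2.6 ± 1.62 CPM (3.87 ± 0.78, edgeR adjusted p = 0.000625), and 2.41 without enzalutamide replicate 4. IFITM1 (3.50), IFI44L (3.44), MX2 (3.28), IFIT2 (3.14), LGALS9 (3.03) and RSAD2 (2.99) passed as well. Without that library they gave 2.14, 2.16, 1.57, 1.67, 1.65 and 1.66, each still past the threshold, and SAMD9L and these genes then ranked below SLPI (3.13), GPA33 (2.78), GC (2.76), FAM3D (2.58) and PIGR (2.51), named after their values were seen. With all samples the latter genes rose with enzalutamide by 2.97 ± 0.40, 2.89 ± 0.26, 2.70 ± 0.32, 2.58 ± 0.29 and 2.59 ± 0.32. Of 23 interferon genes 21 rose (23 adjusted over the list alone, median 1.71, camera adjusted p = 1.13e-05, and adjusted p = 0.599 with an estimated correlation). Without enzalutamide replicate 4 the count was 11 and the median 0.99. In cluster A, which holds that library, all 23 passed the threshold (median 3.34). In cluster B 3 passed (median 0.13) and the camera adjusted p was 0.335.

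**Figure D3:**
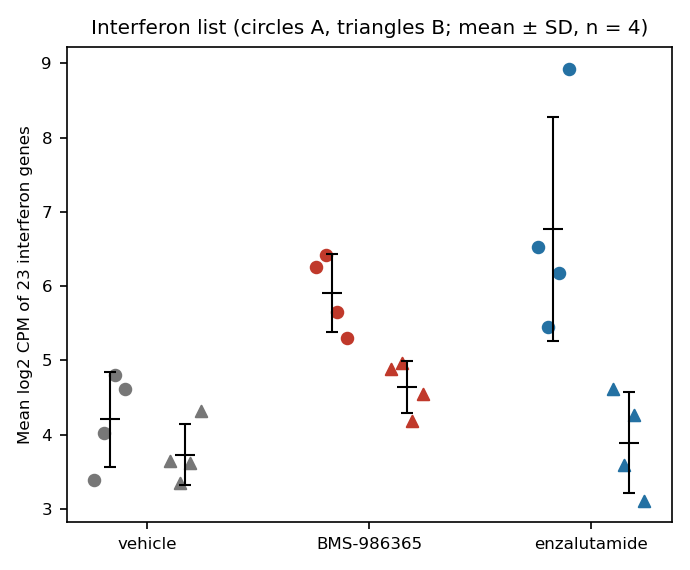
Mean log2 CPM of the 23 tested interferon genes in each sample by treatment, with circles for cluster A, triangles for cluster B and bars for the mean ± SD of 4 samples. Enzalutamide replicate 4 lies at 8.93, against 3.11 to 6.53 in the other enzalutamide samples, 4.19 to 6.42 with BMS-986365 and 3.35 to 4.8 in vehicle.

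The other largest changes with enzalutamide were NXPE1, which rose to 8.7 ± 2.34 CPM from 0.439 ± 0.224 CPM (4.29 ± 0.28, edgeR adjusted p = 8.34e-10), and 8 falls. RPE65 fell by 3.82 ± 0.48, HMOX1 by 2.80 ± 0.63, ANPEP by 2.41 ± 0.49 and ALOX15B by 2.27 ± 0.26. ACSM1, a medium-chain acyl-CoA synthetase, fell to 51.1 ± 44.1 CPM from 216 ± 182 CPM (-2.39 ± 0.22). The hypoxia-induced host gene MIR210HG fell by 2.35 ± 0.40 and SLC16A3, a lactate exporter, by 2.23 ± 0.41, and CHRNA2 was the remaining fall. Neuroendocrine genes had 0 of 17 past the threshold (0 adjusted over the list alone; camera adjusted p = 0.547), but 5 in cluster B, where the camera adjusted p was 0.0245 and became adjusted p = 0.582 with an estimated correlation. Their medians were -0.82 in cluster A and 2.17 in cluster B. Glucocorticoid receptor targets had 2 of 15 higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.451), basal genes 2 of 9 higher (2; 0.48) and genes of epithelial to mesenchymal transition 1 of 9 higher and 2 lower (1 and 2; 0.719). In the last list the calls of ZEB1 and VIM were lost in 4 and 7 of 24 fits that each left out 1 library. Endoplasmic reticulum stress genes had 4 of 17 higher, CALR among them at 0.32, and 2 lower (4 and 2; camera adjusted p = 0.719). Integrated stress response genes had 3 of 16 lower (3, camera adjusted p = 0.346, and adjusted p = 0.877 with an estimated correlation). Without enzalutamide replicate 4 the count was 8 and camera called the list (adjusted p = 0.00172), with the preset correlation only. Their median was 0.24 in cluster A and -0.51 in cluster B, where 7 were lower (camera adjusted p = 0.000841, and adjusted p = 0.268 with an estimated correlation). Among p53 targets 3 of 16 were higher and 4 lower (3 and 5; camera adjusted p = 0.398, fry adjusted p = 0.0498), and 7 lower without that library. Steroid enzymes had 3 of 10 higher and 2 lower (3 and 2; camera adjusted p = 0.789).

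Fibroblast and smooth muscle markers had 2 of 6 higher with enzalutamide, TAGLN (0.42 ± 0.11) and COL1A1 (0.85), and 1 lower, COL3A1 (-0.86; 2 and 1 adjusted over the list alone; camera adjusted p = 0.398). Endothelial markers had ENG higher (0.63 ± 0.18) and VWF lower (-2.00 ± 0.41) of 4 (1 and 1; camera adjusted p = 0.889). LYZ was the 1 myeloid marker of 3 that was higher (1; camera adjusted p = 0.436) and KRT10 the 1 hepatocyte and keratinocyte marker of 5 that was lower (0; camera adjusted p = 0.979), with calls lost in 6 and 10 of the 24 fits without 1 library. In all, edgeR called 6778 of 17603 genes (38.5%), 3310 higher and 3468 lower, and 707 higher and 386 lower by at least 2-fold. Cluster A alone gave 2305 (1090 higher, 1215 lower) and cluster B alone 4441 (2163 higher, 2278 lower). Library size in place of TMM scaling gave 4251 higher against 2573 lower, with a median shift of 0.062. Camera called 10 of 23 lists and 0 with an estimated correlation, and fry called 11, including all 10.

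**Figure D4:**
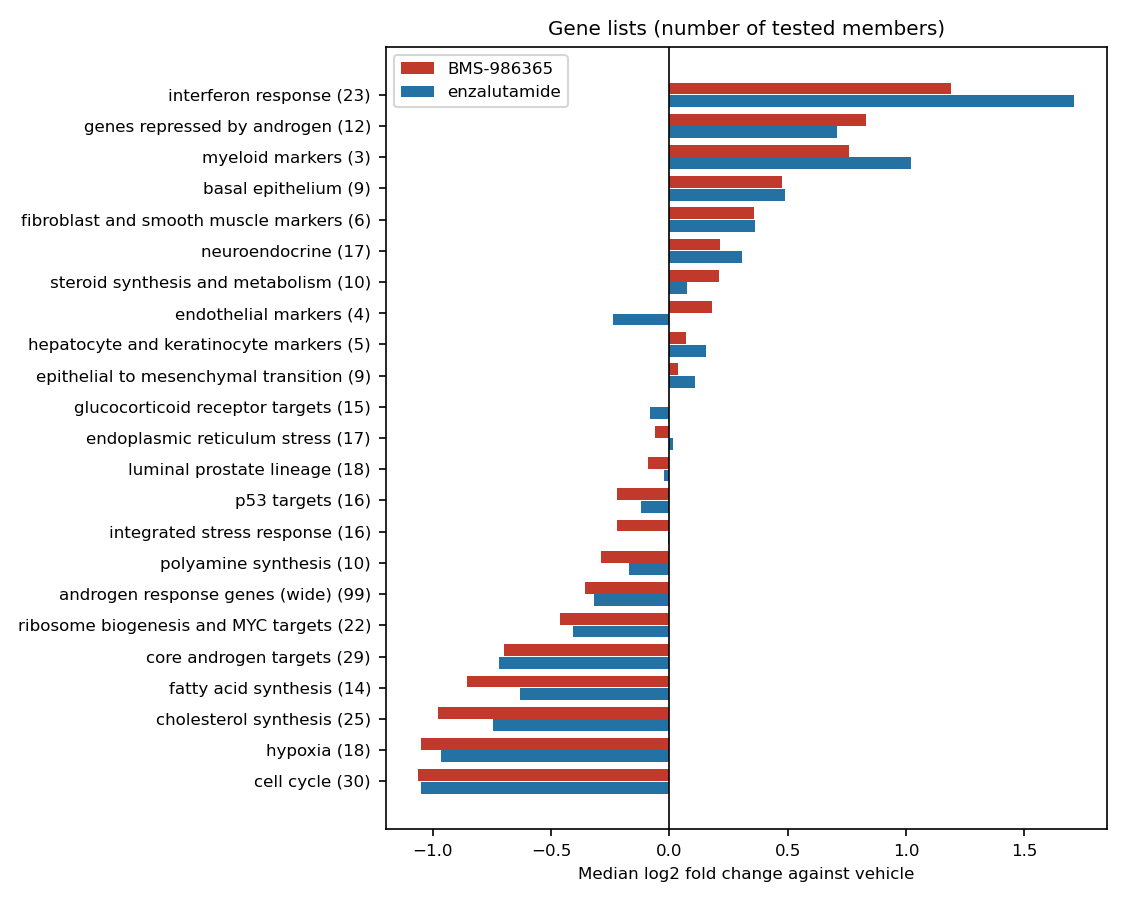
Median log2 fold change against vehicle of the tested members of each gene list, as 1 bar per compound, with the number of members in brackets. The cell cycle list lies at -1.06 with BMS-986365 and -1.05 with enzalutamide, cholesterol synthesis at -0.98 and -0.74, and interferon genes at 1.19 and 1.71.

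The third comparison set the compounds side by side, at doses that differ (60 and 50 mg/kg). No gene passed the threshold in edgeR (0 genes, 635 at an unadjusted p under 0.05, where chance gives 880, smallest adjusted p 0.57), nor in voom (0 genes), while DESeq2 called 1. That gene was FRAS1, an extracellular matrix gene outside the naming rule and chosen after its values were seen. FRAS1 was at 212 ± 35.9 CPM with BMS-986365 and 151 ± 31.8 CPM with enzalutamide (DESeq2 log2 fold change 0.49 ± 0.10, DESeq2 adjusted p = 0.024, edgeR adjusted p = 0.57). Each cluster alone also gave 0 genes in edgeR, with 835 in cluster A and 635 in cluster B at an unadjusted p under 0.05. FASN differed by -0.37 on the log2 scale (95% interval -0.66 to -0.09, edgeR adjusted p = 1). The 95% interval of the difference lay within a 2-fold change for 90.5% of genes and within a 1.5-fold change for 72.3%, with a median half-width of 0.244 on the log2 scale. No list had a member past the threshold over all genes. Adjusted over the list alone, 1 basal gene (KRT5, 1.52 ± 0.38) and 1 glucocorticoid receptor target (NR3C1, 0.34 ± 0.09) were higher with BMS-986365. Camera placed cholesterol synthesis (median -0.11, adjusted p = 0.000195), fatty acid synthesis (-0.20, adjusted p = 0.000195) and endoplasmic reticulum stress genes (-0.15, adjusted p = 7.09e-05) lower with BMS-986365. These calls were lost at adjusted p = 0.94, adjusted p = 0.693 and adjusted p = 0.693 with an estimated correlation, and fry called 0 lists. Within clusters camera called 6 lists in cluster A and 10 in cluster B (lowest adjusted p = 0.658 and adjusted p = 0.361 with an estimated correlation). Interferon genes had a median of -1.27 in cluster A (camera adjusted p = 1.7e-05), which holds enzalutamide replicate 4, and 0.69 in cluster B (2.2e-14). Basal genes had -0.90 (0.021) and 0.85 (7.59e-06). Camera called 4 lists for the difference between clusters, these among them, and 0 with an estimated correlation (lowest adjusted p = 0.177 with an estimated correlation).

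The log2 fold changes of the compounds against vehicle had a Pearson r of 0.919 and a Spearman rho of 0.919 across 17603 genes, which are not independent replicates. Both comparisons share the vehicle samples: simulated groups with no effect, with each gene drawn independently, gave r from 0.465 to 0.522 over 20 runs. With the vehicle samples split between the comparisons in 36 ways, r ran from 0.682 to 0.782 (mean 0.74). The covariance was 0.271, against 0.0284 in the simulations, a difference of 0.243, and 0.246 on average over the splits. Both compounds raised 2801 genes and lowered 3109, and 0 genes were called in opposite directions. With the vehicle samples split, both raised 1313 to 1540 genes and lowered 1672 to 2043, and at most 3 were called in opposite directions. NXPE1, CLU and FOLH1 were among those that rose with both, and FASN and CHRNA2 among those that fell.

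**Figure D5:**
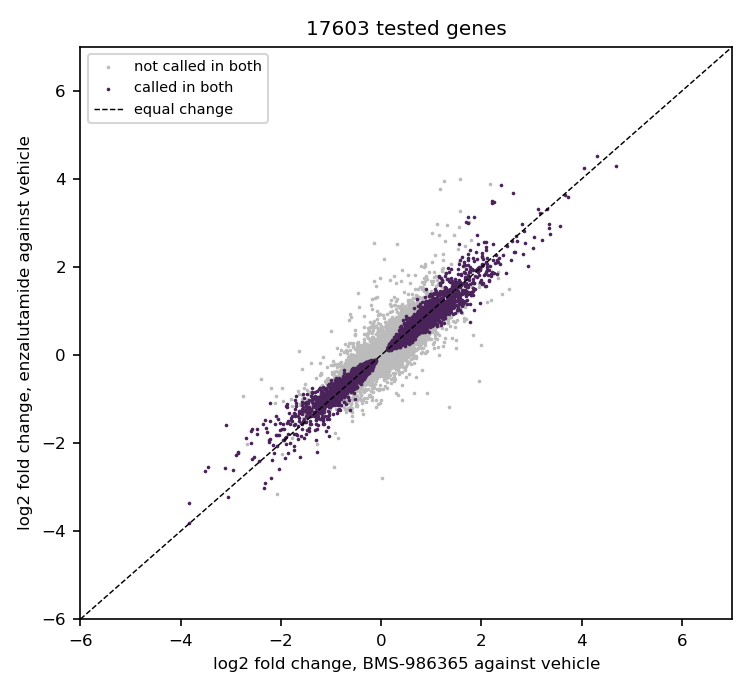
Log2 fold changes against vehicle of 17603 genes with BMS-986365 (x axis) and with enzalutamide (y axis), with genes called in both comparisons in dark and a dashed line of equal change. The points follow the line (Pearson r 0.919), and 0 genes called in both lie in opposite directions.

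Whether either compound acted differently in the clusters was tested by an interaction term. For BMS-986365 edgeR called 0 genes (2017 at an unadjusted p under 0.05, where chance gives 880, smallest adjusted p 0.123), and DESeq2 called 74. For enzalutamide edgeR called 0 genes (1900, smallest adjusted p 0.187), and DESeq2 called 112. Camera with the preset correlation called 12 of 23 lists for this difference with BMS-986365 and 9 with enzalutamide, the cell cycle (adjusted p = 1.94e-11 and 1.03e-07), hypoxia and interferon lists among them. All calls were lost with estimated correlations (lowest adjusted p = 0.217 and adjusted p = 0.0753 with an estimated correlation). A further 46 tests of lists permuted the cluster labels within each treatment, on values centred per cluster, which makes their p-values approximate. Of these tests 15 were under 0.05 unadjusted and 0 after adjustment. The lowest adjusted permutation p was 0.0561, for cholesterol synthesis with enzalutamide. For the cell cycle, the smaller count of calls in cluster A is thus not a difference shown by these tests on samples.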

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

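The tests in this part on the interferon genes of 1 library and on the origin of the clusters were chosen only after the result was seen, and the splits of the samples were planned. Among 78 tests for a sample far from the others of its treatment (Dixon's test, 8 samples each), 7 found one, where chance gives about 1 in 20. All were mean log2 CPM values over a gene list. The 8 samples of a treatment came from both clusters, and the lists share genes and samples, so 1 in 20 is only a rough reference. Vehicle replicate 2 was at 5.56 for the cell cycle (other vehicle samples 6.1 to 6.57). Vehicle replicate 1 was at 7.83 for fatty acid synthesis (others 8.13 to 8.37) and 7.21 for ribosome biogenesis and MYC targets (others 6.73 to 6.85). BMS-986365 replicate 3 was at 5.48 for glucocorticoid receptor targets (others 4.62 to 4.91), replicate 4 at 6.61 for cholesterol synthesis (others 5.69 to 6.01) and replicate 6 at 5.66 for hypoxia (others 4.99 to 5.25). Enzalutamide replicate 4 was at 6.47 for the integrated stress response (others 4.39 to 5).

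Enzalutamide replicate 4 also had the highest interferon genes, at a mean log2 CPM of 8.93 against 3.11 to 6.53 in the other enzalutamide samples. Leukocytes in that tumour stay open: 21 human leukocyte markers summed to 2.63 CPM there and to 1.12 to 3.02 CPM in the other 23 libraries. Leukocytes of the host are mouse cells, however, which counts of human genes may not measure. The count columns carry the ending Human, but how mouse reads were set apart is not given. The count of members did not decide whether that library alone carries the rise of the list. Without it 11 members still passed, a number that lies between those set in advance for either answer. Within cluster A the sample values argue against it: enzalutamide replicates 1 to 3 lay at 6.53, 5.45 and 6.18, and vehicle replicates 1 to 4 at 3.39, 4.02, 4.8 and 4.62. In cluster B the median log2 fold change of the list was 0.13. No biological explanation was tested.

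The samples fell into 2 sets of 12 that no treatment, dose or model label separates. By the running numbers of the sample titles the sets are 2 successive blocks, each holding every treatment. This order cannot tell a tumour model from a batch. Depth is argued against as the cause, since 0 samples changed set when every library was thinned to the smallest total, 18634881 counts. Stromal cells stay open: 10 samples of cluster A lay within the range of cluster B for the sum of 25 human stromal markers (32.2 to 82 CPM), but stroma of the host is mouse tissue. That the sets are 2 different tumours stays open too, as the design text named 2 models. Between the sets edgeR called 8814 genes, 1260 of them at least 2-fold. The sets were found in these same counts, so the number of genes speaks for no particular cause. A count of genes at 10 CPM or more in every sample of 1 set and under 1 CPM in every sample of the other gave 0. None of 100 random splits gave such a gene either. The rule written before this test took that outcome as one against 2 different tumours. A count of 0 in the sets and in the random splits cannot tell them apart, however, so no conclusion is drawn from it. The count also left out the genes kept from naming (Y-linked genes, XIST, HLA genes and genes often deleted in the germline), which can differ between patients. A processing batch, passage or site of growth stays open as well, because the labels give none.

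Chance is argued against for both comparisons against vehicle by refits with treatment labels swapped within clusters, though 1 of 50 is the smallest share that these splits can reach. With BMS-986365, 7539 genes were called and the highest of the other splits gave 1, so that 1 of 50 splits, the real one, gave as many. With enzalutamide, 6778 genes were called and the highest other split gave 3281 (1 of 50), a split close to the real one with labels reversed. Between the compounds and for both interactions the real count was 0, which every split must reach (50 of 50), so the splits decide nothing there. The highest other splits there gave 1 gene between the compounds, 433 for the interaction with BMS-986365 and 4034 for that with enzalutamide, the last where 3 of 4 labels were exchanged in cluster A and 0 in cluster B, and these counts point to the treatment effect as a structure of the samples.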

How the results depend on the processing

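The fit without enzalutamide replicate 4 and vehicle replicate 1 together was chosen after seeing the data. The counts of genes against vehicle stayed within 1.5 times of 7539 (BMS-986365) and 6778 (enzalutamide) under all alternatives but these: cluster A alone (2414 and 2305), cluster B alone for enzalutamide (4441) and a minimum fold of 2 (1155 and 1093), which use fewer samples or a stricter call. No cluster term gave 5512 and 4783, of which 5510 and 4774 were also called with it, and the fit without both libraries gave 8181 and 6781. Between the compounds DESeq2 called 1 gene, and for the interactions it called 74 and 112, where edgeR called 0. In the simulated comparisons, which held no interaction test, DESeq2 gave more false calls than edgeR. Those counts were drawn from edgeR's own fit, which may favour edgeR, so they do not decide whether the DESeq2 calls are false. KLK3 and KLK2 turned from lower to higher with BMS-986365 when surrogate variables replaced the cluster term, at 0.529 (edgeR adjusted p = 0.0336) and 0.484 (edgeR adjusted p = 0.0447). The list of core androgen targets lost its call with an estimated correlation (adjusted p = 0.392 and 0.433), and the correlation of the compounds fell from 0.919 to 0.74 with the vehicle samples split. Where fewer samples or a stricter call do not account for it, the cause was not tested. Leaving out 1 library at a time gave 6748 to 7854 genes with BMS-986365, 6118 to 6962 with enzalutamide and 0 to 0 between the compounds. The camera adjusted p of the core androgen targets then ran from 1.13e-05 to 0.00071 and from 3.16e-05 to 0.00301. Scaling by the ERCC spike-in could not be run, as all its values were 0. No paired analysis was possible because the replicate numbers were given in accession order. The depth and the spread of 8 samples per treatment can hide some changes under 2-fold. Most calls against vehicle were smaller than that all the same, since 1155 of 7539 and 1093 of 6778 reached 2-fold.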

Other observations

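The tests of the gut and liver list, of the interval widths and of the shift score were chosen only after the result was seen, and the genes named here that lie outside the naming rule were chosen after their values were seen. Some genes of gut and liver epithelium stood among the largest rises with BMS-986365. They were GPA33, PIGR, GC and FAM3D, which rose with enzalutamide as well (2.89 ± 0.26, 2.59 ± 0.32, 2.70 ± 0.32 and 2.58 ± 0.29). One hypothesis is that a wider programme of such genes may rise when androgen signalling is inhibited. A list of 36 genes of gut and liver epithelium, 26 of them tested, was written without these 4. Of its members, the membrane protein gene TSPAN8 rose to 311 ± 66.5 CPM with BMS-986365 and 322 ± 76.1 CPM with enzalutamide from 104 ± 45.4 CPM in vehicle (SD, n = 8 each; log2 fold change 1.62 ± 0.17 and 1.65 ± 0.17; edgeR adjusted p = 3.63e-07 and 6.36e-07). The mucin gene MUC13 rose by 1.16 ± 0.25 with each, and HNF4G, a nuclear receptor of gut and liver, rose by 0.87 ± 0.14 and 0.81 ± 0.14. Without enzalutamide replicate 4 the rises of TSPAN8, MUC13 and HNF4G with enzalutamide were 1.60, 0.82 and 0.78. The list as a whole was not tested without that library. In all, 9 members rose and 0 fell with BMS-986365 in edgeR (median log2 fold change 0.76), and with enzalutamide 12 rose and 0 fell (median 0.85). The list's mean log2 CPM lay above vehicle by 0.389 in cluster A and 0.861 in cluster B with BMS-986365, and by 0.796 and 0.499 with enzalutamide. The list's mean log2 CPM differed from vehicle by exact permutation within clusters (p = 0.00898 and p = 0.00408, two-sided, 4900 permutations each), and camera, which compares the list with other genes, gave p = 0.00185 and p = 0.000956. Estimated correlations gave p = 0.254 and p = 0.228, and fry gave p = 0.00282 and p = 0.0029, so the rise beyond that of other genes rests on the preset correlation.

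No gene passed the threshold between the compounds in edgeR, and a candidate explanation is that the compounds shift the same genes by similar amounts. Across the splits of the vehicle samples the correlation of the log2 fold changes was at least 0.682, above the highest value of 0.522 in simulated unchanged groups. The simulated groups are not a matched reference for the splits. Their comparisons shared all vehicle samples, while those of the splits shared none, and their genes were drawn independently. A spread too wide to exclude 2-fold differences is argued against, since 90.5% of genes had a 95% interval within a 2-fold change. Of the 5910 genes called with both compounds, 65.1% had the larger change with BMS-986365, with a median ratio of the log2 fold changes of 1.07. A larger shift with BMS-986365 was not shown: the score of these genes (mean log2 CPM of those higher minus that of those lower, relative to vehicle) was 1.27 ± 0.29 with BMS-986365 and 1.19 ± 0.225 with enzalutamide (SD, n = 8 each; exact permutation p = 0.456, two-sided, 4900 permutations within clusters), with differences of 0.000599 in cluster A and 0.156 in cluster B.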
